A study of Escherichia coli str. K-12 substr. MG1655 with 2 samples.

How the data were processed

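ChIP-exo was performed on Escherichia coli K-12 MG1655 cells in which the transcription factor Cra carried a myc epitope tag. ChIP-exo is chromatin immunoprecipitation followed by exonuclease digestion, which trims each strand of the precipitated DNA up to the crosslinked protein. Per the labels' protocols, cells were grown aerobically at 37 °C to mid-log phase in M9 minimal medium with 0.2% galactose, crosslinked in 1% formaldehyde for 25 min and precipitated with an anti-myc antibody. There were 2 libraries, which the series' design text describes as biological replicates, and they form 1 group. No library of an untagged strain, of input DNA or of another carbon source was analysed here, so no comparison between conditions was made.

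The authors deposited, for each library, a coverage signal, which is the number of aligned reads over each position of each strand. Only positions above 0 are listed, and the values are whole numbers with no scaling for depth. Bowtie 1.0.0 and the genome build ASM584v2 are named in the submitters' processing notes. Alignment settings, duplicate removal and the handling of reads with several matches are not given in the sources used here. Each library has its own file, so the replicates were not pooled.

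The coverage was resolved into reads. The shortest isolated run of covered positions was 31 bp in both libraries. With a read length of 31 bp, each coverage value resolved into whole reads with 0 negative counts, and the reads summed back to the deposited coverage at every position, whereas a length of 30 bp gave 4542374 negative counts in replicate 1 and a length of 32 bp gave 4741460. The 5' end of each read was taken from this decomposition. Replicate 1 held 2419039 reads at 114941 occupied strand positions, and replicate 2 held 2728944 reads at 234798. Thus a position with any read held 21.0 reads on average in replicate 1 and 11.6 in replicate 2. Identical reads need not be independent molecules, though the exonuclease can also stop separate molecules at the same base. The coverage does not tell these apart. The Wilson 95% intervals given for shares of reads treat every read as independent. They are therefore too narrow for the counting error of molecules, and they leave out the spread between libraries.

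The positions in the files were compared with the gene table of ASM584v2 before any use of its coordinates. The last covered position was 4639673, and 3 genes of that table start beyond it. Coverage over the 16S rRNA gene rrsH was compared with coverage at rrsC, rrsA, rrsB and rrsE over shifts of the table positions. The best match lay at a shift of 1977 bp for 4 of the 4 genes, with correlations from 0.82 to 0.90, and the highest correlation more than 100 bp away from that shift was 0.44. The files therefore use another coordinate system than the build named in the notes. Which release of the MG1655 chromosome it is is not given in the sources used here. Positions below are those of the deposited files, 1-based, and no gene name, exon or promoter was assigned to them, because coordinates were not converted between builds. No genome sequence was used here. The planned tests of promoter location, of matches to the Cra consensus sequence, of borders relative to that sequence and of fixed gene lists (known Cra targets, pathways of carbon metabolism, ribosomal protein operons and comparison lists) were for these reasons not run, and rRNA and tRNA genes were not set apart.

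Sites were called by a rule fixed before the data were examined. Coverage was averaged in windows of 100 bp placed every 10 bp. The fold of a window was its mean over the median of windows within 10 kb on either side, after 0.1 of the strand's mean coverage was added to both. The score of a library was the lower of the folds of the 2 strands. The log2 score was compared with a normal distribution that had the median and the lower-half spread of all windows, and p-values were adjusted by Benjamini-Hochberg. A site needed an adjusted p under 0.01 and a score of at least 3 in both libraries, windows within 100 bp were merged, and the window with the highest geometric mean score was the summit. The lower-half spread was 1.04 on the log2 scale in replicate 1 and 1.76 in replicate 2, so that a score of 3.74 passed in replicate 1 and 189 was needed in replicate 2. After this was seen, a rule on the score alone, at least 10 in both libraries, was added. Libraries were simulated with the real numbers of occupied positions, placed uniformly at random. Reads per position were drawn from the real values without the highest ones. In these libraries the planned rule recovered 40 of 40 planted sites of 200-fold and 4 of 40 of 50-fold, and 0 of 40 at each of 5-, 10- and 20-fold. The rule on the score alone recovered 40 of 40 at each of 20-, 50- and 200-fold, 11 of 40 at 10-fold and 0 of 40 at 5-fold. Both called 0 sites away from the planted ones, but a uniform background cannot show how often either rule calls false sites in the real libraries.

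The number of sites shared by chance came from 1000 circular shifts of replicate 2 against replicate 1, by at least 20 kb, as a one-sided permutation test whose smallest p is 0.001. Reads of a site were counted by their 5' ends within 75 bp of the summit. The strand separation was the median position of reverse 5' ends minus that of forward 5' ends, with bootstrap intervals over sites from 10000 draws. A border was the position with the most 5' ends on a strand, and borders of the libraries were called the same when at most 2 bp apart. Chance for this came from 10000 pairings of the libraries across sites, as a one-sided permutation test whose smallest p is 0.0001. Profile agreement was Pearson's r between the libraries' 5' end counts over both strands of the 151 bp around a summit. The named sites were the 25 with the highest geometric mean score. The fixed naming rule asked for sites in promoter regions found by the planned rule, which could not be applied. Alternatives changed the window, the background, the treatment of strands, the highest positions, the depth, the thresholds and the libraries used, and another counted each occupied 5' end once. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.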

Results

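Binding of Cra to the chromosome was mapped by ChIP-exo in E. coli MG1655 growing on galactose. Cra, also called FruR, is a regulator of the LacI family that represses genes of glycolysis and activates genes of gluconeogenesis. The 2 replicate libraries of the epitope-tagged strain held 2419039 and 2728944 reads of 31 bp. Forward reads made up 51.4% of replicate 1 and 51.6% of replicate 2. Reads covered 25.3% of strand positions in replicate 1 and 44.9% in replicate 2. The data address where on the chromosome Cra was bound under this condition and how well the libraries agree on each site. Positions are those of the deposited files, whose coordinate system differs from the ASM584v2 gene table, so sites are given by position and not by gene.

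The strongest binding lay at 5 sites, which were the only ones to pass the planned rule in both libraries. The site at 2261561 exceeded every other site, with a score (fold over local background on the weaker strand) of 1520 ± 172 (SD, n = 2). It was followed by the site at 2531531, with a score of 852 ± 192 (SD, n = 2). The sites at 331081, 3071821 and 3889571 had scores of 394 ± 134, 340 ± 66.6 and 259 ± 51.5 (SD, n = 2 each). Circular shifts of one library against the other gave 0.518 shared sites on average and at most 3 (permutation test, p = 0.001, one-sided, the smallest the shifts can give). With each occupied 5' end counted once, which limits the coverage of a strand to 31 and so the score of the densest sites, the geometric mean score was 52.2 at 2261561, 47.3 at 2531531 and 46.1 at 331081, and the site at 1753511 was level with the first at 52.4. The rule required a score of 189 in replicate 2 but 3.74 in replicate 1, and replicate 1 alone gave 2602 sites. The calls depended on the settings, with 0 sites when the strands were added or the highest positions capped, and 2 with a genome-wide background or an adjusted p under 0.001. A window of 50 bp gave 364.

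A small number of positions took a part of the reads that was large for their length, though most reads lay elsewhere. The 151 bp around the summit at 2261561 held 4.01% of the reads of replicate 1 (95% Wilson interval 3.99 to 4.04) and 4.07% of those of replicate 2 (4.05 to 4.09). The site at 2531531 held 1.81% and 1.65%. The 5 sites together held 7.35% and 7.29%, and the 25 strongest sites 9.82% and 9.52%. The ordering of the sites at 2261561 and 2531531 was the same in both libraries.

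With the score alone, 95 sites reached at least 10 in both libraries, against 1.62 on average and at most 8 in the circular shifts (permutation test, p = 0.001, one-sided, the smallest possible). At least 20 was reached by 30 sites against a mean of 0.108, and at least 50 by 14 against 0.014. With each 5' end counted once, 100 sites reached at least 10, 23 reached at least 20 and 0 reached at least 50 in both libraries, where 5 did so in replicate 1 and 0 in replicate 2. At a minimum of 3, 459 sites were shared against a mean of 169, so sharing by chance makes up more of the weakest sites than of the strong ones. The shifts account for noise that differs between the libraries. Background that recurs in both, which a library of an untagged strain would show, is not covered by this test.

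**Figure D1:**
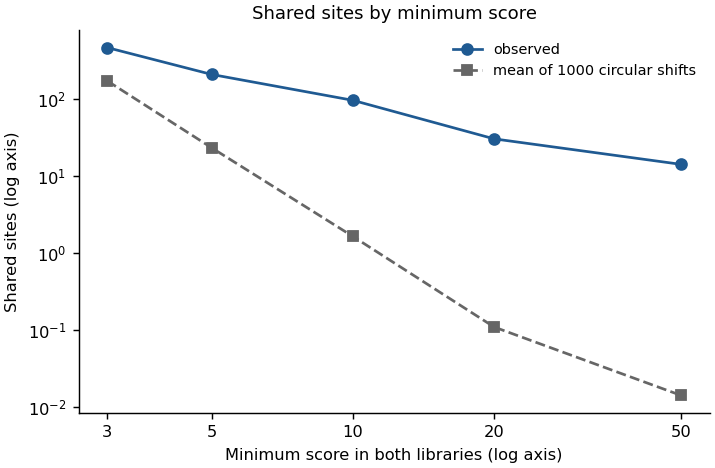
Number of sites shared by both libraries (vertical log axis) against the minimum score required in each library (horizontal log axis), observed (circles) and as the mean of 1000 circular shifts (squares). The observed number fell from 459 at a score of 3 to 14 at a score of 50, and the mean of the shifts from 169 to 0.014.

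A further 7 sites brought the number with a geometric mean score above 90 to 12. The sites at 2276201, 4105471, 1899971 and 2906761 had scores of 158 ± 15.5, 141 ± 7.49, 113 ± 3.14 and 105 ± 20.9 (SD, n = 2 each). The site at 1753511 reached 274 in replicate 1 and 88.1 in replicate 2, a ratio of 3.11, while its share of reads was 0.172% and 0.143%. A pair of sites lay 620 bp apart, at 1860681 with a score of 145 ± 62.8 and at 1860061 with 93.3 ± 29.4 (SD, n = 2 each).

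The sites ranked 13 to 25 had scores between about 27 and 65. The highest was at 169901, with 65.1 ± 21.6, followed by 3980631 with 66.9 in replicate 1 and 53.0 in replicate 2. The next were 2507601 with 57.2 ± 17.8 and 1990111 with 57.6 ± 33.5 (SD, n = 2 each). The sites at 3717951 and 1297601 had scores of 46.0 ± 14.5 and 42.1 ± 2.04 (SD, n = 2 each). At 2816431 the libraries gave 36.3 and 36.3, and at 2403371 they gave 26.9 and 26.4. The sites at 2518981, 2920521 and 2922411 had scores of 32.5 ± 10.1, 29.7 ± 0.138 and 28.7 ± 1.55 (SD, n = 2 each), and the last 2 of these lay 1890 bp apart. The highest ratios of replicate 1 to replicate 2 among these were at 1049891, with 52.3 in replicate 1 and 14.6 in replicate 2, and at 2689281, with 52.6 and 21.3. The shares of reads differed less between the libraries. They were 0.0233% in replicate 1 and 0.0255% in replicate 2 at 1049891, and 0.0593% and 0.0460% at 2689281.

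**Figure D2:**
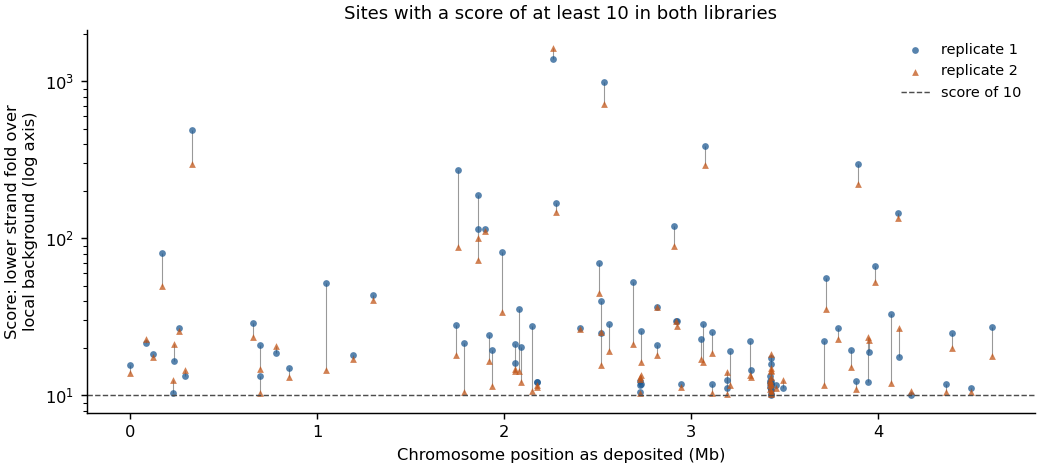
Score (lower strand fold over local background, log axis) of the 95 sites against chromosome position in Mb, with circles for replicate 1, triangles for replicate 2 and a grey line joining the libraries at each site. The site at 2261561 stands highest in both libraries, at 1398 and 1642, and the dense column between 3421431 and 3427011 holds 13 sites.

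Across the 25 strongest sites the log2 scores gave Pearson's r = 0.95 and Spearman's rho = 0.91, and across the 70 other sites r = 0.54 and rho = 0.54. Across all 463968 windows r was 0.29 and rho 0.22. These are correlations across sites or overlapping windows, which are not independent replicates, and the sites were chosen for high scores in both libraries. The 25 strongest sites span a far wider range of scores than the 70 others, which by itself raises r, so these values do not rank the agreement of the sets. The ratio of replicate 1 to replicate 2 had a median of 1.33 (range 0.85 to 3.58) at the 25 strongest sites, with 23 of the 25 higher in replicate 1. At the 70 others it had a median of 1.11 (range 0.52 to 2.74), with 50 of the 70 higher in replicate 1. The score also depends on the local background and on the mean coverage of the library. These ratios are therefore not ratios of the reads at a site, and the share of reads could differ in the other direction.

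Most exonuclease borders of the 12 strongest sites fell within 2 bp of each other in the libraries. At 2261561 the most frequent forward 5' end was at 2261543 and the most frequent reverse 5' end at 2261611 in both, 68 bp apart. At 2531531 these were at 2531535 and 2531574, 39 bp apart, and at 3071821 at 3071828 and 3071842, 14 bp apart. At 2276201 they were at 2276172 and 2276202, 30 bp apart, and at 169901 at 169871 and 169916, 45 bp apart. Among the 12 strongest sites, 18 of 24 borders were the same within 2 bp, against a mean of 2.52 and at most 11 in the pairings across sites (permutation test, p = 0.0001, one-sided, the smallest possible). The other 6 borders differed, among them the reverse border of 331081, at 331116 in replicate 1 and 331122 in replicate 2, and the forward border of 4105471, at 4105414 and 4105438. Among ranks 13 to 25, 5 of 26 were the same, against a mean of 1.76 (permutation test, p = 0.025, one-sided).

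Single bases carried a substantial part of the 5' ends of a strand at some sites. The forward border at 2906729, of the site at 2906761, held 20.1% of the forward 5' ends of the site in replicate 1 and 22.6% in replicate 2. At 169871 the values were 25.5% and 15.6%. At the strongest site, 2261561, the forward border held 11.8% and 11.3%. A high share alone does not show a fixed border, since it can arise where few positions are occupied. At the weaker site at 2088091 the top forward base held 29.4% in replicate 1, with 10 occupied forward positions. In replicate 2 it held 11.8%, with 23, and the profiles of the libraries correlated at only 0.06.

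Forward 5' ends lay to the left of reverse 5' ends at 25 of the 25 strongest sites in each library. The median strand separation was 36 bp in replicate 1 (95% bootstrap interval 32 to 43) and 39 bp in replicate 2 (32 to 43). The 52 sites ranked below 25 that lay outside stretches of at least 3 sites within 5 kb gave similar medians. These were 36 bp in replicate 1 (32 to 41) and 34 bp in replicate 2 (26 to 40.5), so this separation is not particular to the strongest sites. Among the 12 strongest sites the mean separation of the libraries ranged from 27 bp, at 3071821, to 46.5 bp, at 2261561. The site at 3980631 had the lowest separation of the 25 sites, 1 and 2 bp. A window that is chosen for coverage on both strands favours a positive separation, so the sign alone carries little information. The size is limited too, because forward 5' ends are the left ends and reverse 5' ends the right ends of 31 bp reads. Reads of both strands that cover the same bases are thus separated by about the read length. The medians therefore do not measure the length of DNA covered by Cra.

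The profile of 5' ends over a site was compared between the libraries base by base. Pearson's r was 0.98 at 2261561, 0.97 at 2531531, 0.97 at 3071821, 0.95 at 3889571 and 0.93 at 331081. It was above 0.246, the value under which 99% of 8930 mismatched pairs of sites fell, at 12 of the 12 strongest sites, at 7 of the 13 sites ranked 13 to 25, and at 30 of the 70 sites ranked lower. Of these 70, the 52 outside stretches of at least 3 sites within 5 kb gave 14 of the 30. At a mismatch threshold of this kind about 1% of sites would pass by chance. The sites at 2507601 and 169901 had r of 0.81 and 0.78, and the site at 2561451, ranked 29 with a score of 23.8 ± 6.57 (SD, n = 2), had r = 0.73. By contrast, r was 0.04 at 3717951, 0.08 at 2922411, 0.09 at 1049891 and 0.11 at 2689281, and 0.31 at 3980631 was not far above the limit.

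**Figure D3:**
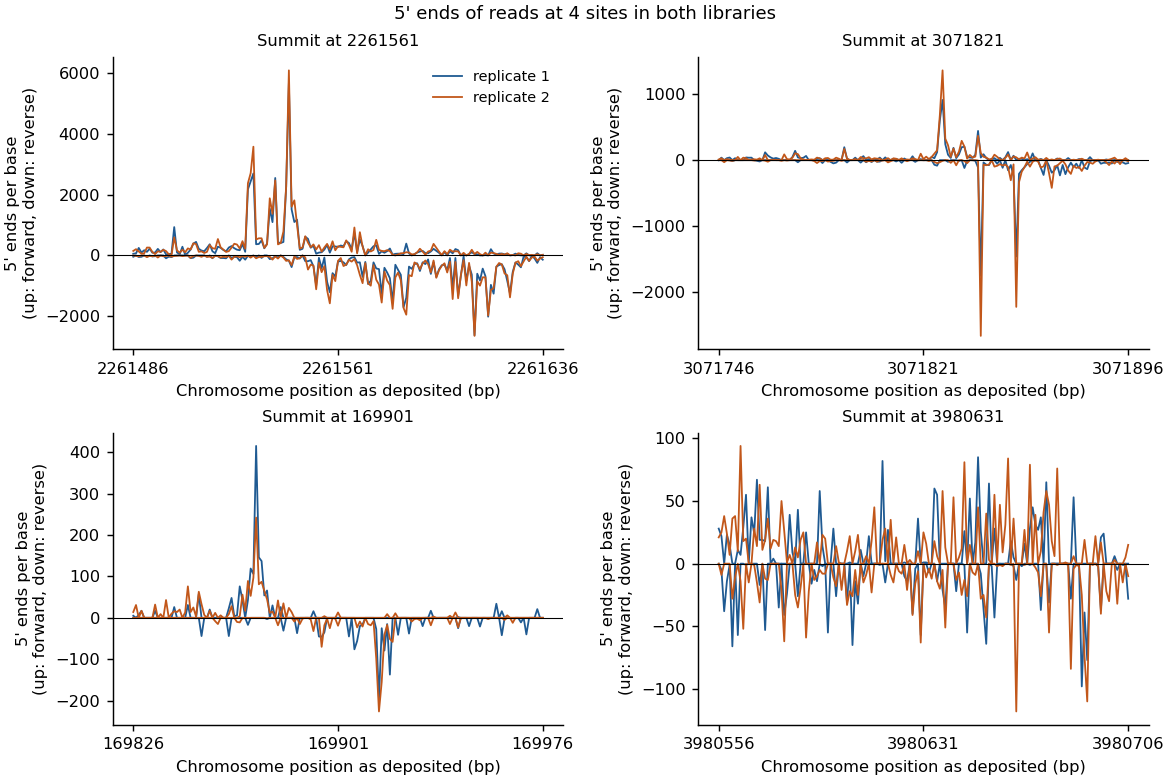
Number of read 5' ends per base, forward above and reverse below the axis, within 75 bp of the summits at 2261561, 3071821, 169901 and 3980631, with replicate 1 in blue and replicate 2 in orange. At the first 3 sites the highest forward and reverse positions coincide between the libraries, and at 3980631 they do not.

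**Figure D4:**
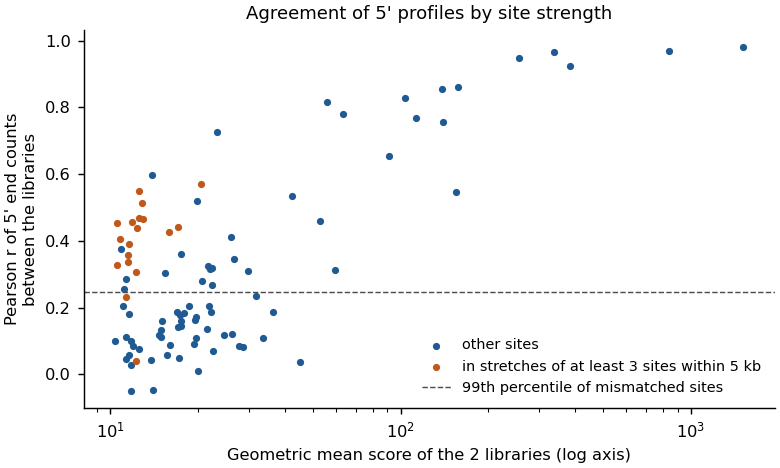
Pearson's r of 5' end counts between the libraries (vertical axis) against the geometric mean score of the 95 sites (horizontal log axis), with sites in stretches of at least 3 sites within 5 kb in orange. The 6 sites with the highest scores have r from 0.86 to 0.98, and the dashed line marks 0.246.

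Part of the weaker signal lay in long stretches and not at single sites. With each occupied 5' end counted once, windows with a score of at least 5 in both libraries were joined across gaps of up to 1 kb. This gave 7 stretches of at least 3 kb, from 3090 to 5590 bp long. They began at 223501, 2172141, 2724061, 3421431, 3939551, 4033271 and 4164401. They held 6.80% of the reads of replicate 1 and 7.41% of replicate 2, and 22 of the 95 sites. The stretch from 3421431 to 3427011 alone held 13 sites, with 1.78% and 1.94% of the reads. None of the 25 strongest sites lay in a stretch of at least 3 sites within 5 kb. In such stretches, 18 sites had a median strand separation of 18 bp in replicate 1 (95% bootstrap interval -5.5 to 29) and 7 bp in replicate 2 (-3 to 14).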

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

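The settings that used the score alone, that counted each 5' end once or that left out the stretches were chosen after seeing the data. The count of 5 sites from the planned rule did not change with a window of 200 bp or the deeper library thinned, and both kept the same 5 sites. A minimum score of 2, 5 or 10 also left 5, but says nothing of stability, since the p criterion already required 189 in replicate 2. It became 364 with a window of 50 bp, 2 with a genome-wide background, 2 with an adjusted p under 0.001, and 0 with the strands added or with the highest positions capped. At an unadjusted p under 0.05 from the same normal null, the rule gave 87 sites with the strands added, 245 with the highest positions capped and 279 at the original settings. Leaving out a replicate gave between 5 and 2602 sites, the higher number without replicate 2. The score alone gave 206, 95 and 30 sites at minimums of 5, 10 and 20, and 100 at 10 with each 5' end counted once. At the planned minimum score of 3, leaving out the p criterion gave 459 sites; for the window, background, strands and capping the cause was not tested. The count of 95 sites became 151 with a window of 50 bp and between 115 and 268 when a replicate was left out, with the higher number without replicate 2; the other settings gave 66 to 133. Of the 95 sites, 63 were called with each 5' end counted once, 66 with a window of 200 bp, 74 with a genome-wide background and 79 with the strands added, and of the 25 strongest, 23 to 25 in each of these settings. The correlation of log2 scores over all windows lay between 0.26 and 0.38. The alternatives for promoter regions, motif matches, gene lists and borders at motifs, and that of rRNA and tRNA sites, were not run. No paired analysis was possible because there was 1 group. Replicate 1 held 114941 occupied 5' ends and replicate 2 held 234798, so the reads are not as many independent fragments.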

Other observations

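The test of neighbouring sites and the comparison of the 16S rRNA gene copies were chosen after the result was seen, and the others were set down before their results. Outside the sites and the 7 long stretches, the number of occupied 5' ends per kb varied along the chromosome in a similar way in both libraries. The rRNA genes were not set apart, so any that lie outside these stretches count in the bins. Over 23 bins of 200 kb, which end at 4600000 and leave out the remainder with 1 of the 95 sites, it was highest between 4200001 and 4400000, at 31.2 per kb in replicate 1 and 60.3 in replicate 2. It was lowest between 1400001 and 1600000, at 14.7 and 32.4, a ratio of 2.12 in replicate 1 and 1.86 in replicate 2. Sites with a score of at least 10 were found in 21 of the 23 bins.

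Sites tended to have close neighbours. With stretches of at least 3 sites within 5 kb left out, 16 of 77 sites had another within 2 kb, against 4.90 on average in 10000 random placements (permutation test, p = 0.002, one-sided). The pairs include 1860061 and 1860681, 620 bp apart, 2920521 and 2922411, 1890 bp apart, and 2815851 and 2816431, 580 bp apart. In the last pair the windows of the first site end at 2815881 and those of the second begin at 2815991. This is just past the limit of 100 bp for merging, so this pair may be 1 wide site. The hypothesis is that some bound regions hold more than 1 contact; the values, 16 against 4.90, may equally come from wide sites that the calling divided, and 2 of the 16, at 2173891 and 2174231, lie in a long stretch of raised signal.

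A relation between the strength of a site and its strand separation was tested across the 30 strongest sites and not found. The read length sets part of the separation, so the test says little about the length of DNA covered by Cra. Spearman's rho was -0.001 (permutation test, p = 0.995) and Pearson's r 0.09 (permutation test, p = 0.628); without the 2 sites farthest from the median strength r was -0.06. These 2 measures of 1 relation were the only ones in the family.

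The sites with a score of 3 to 10, which are the most numerous, could be copies of few amplified fragments, since an occupied position held 21.0 reads on average in replicate 1. Counting each occupied 5' end once argues against this as the whole cause. Counted so, 322 sites of this score were shared by both libraries, where 1000 circular shifts gave 65.0 on average and at most 94. Of the 385 such sites called with all reads, 247 lay within 100 bp of a shared score of at least 3 when each 5' end was counted once, and for the others amplified copies stay open. What stays open is background that recurs in both libraries without Cra, which no library analysed here measures, and weak binding by Cra.

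The long stretches of raised signal may be the rRNA operons, which are repeated sequences and heavily transcribed. This is open. Coverage at 4 of 4 other 16S genes matched that at rrsH at the same shift of 1977 bp, which shows an offset between coordinate systems. The positions of these genes were not set against those of the stretches, so the match by itself does not place the stretches. The stretch at 2172141 is the shortest, at 3090 bp, and the best partners of its sites at 2173891 and 2174231 correlated at only 0.18 and 0.23. The 18 sites in stretches of at least 3 within 5 kb lie in only 2 of the 7 long stretches, those at 2724061 and 3421431. Of these, 6 had a profile that correlated at 0.8 or more with a site at least 5 kb away, against 0 of the 77 other sites. This is short of the 9 that shared reads would need as set beforehand and above the limit for excluding them. The 6, at 2724931, 2726731, 2728761, 3422531, 3424331 and 3426371, correlated at 0.96, and the next highest of the 18 was 0.45. At these 6 the values go with reads shared among repeated copies. For the others, where only called sites could serve as partners, this stays open. Fixed borders were the same in both libraries at 6 of 36 borders, against 7 at most in 10000 pairings (permutation test, p = 0.0011, one-sided); this falls within the range set beforehand for no fixed borders, but that range was too wide, because few pairings came so high. Enrichment of transcribed DNA without Cra and binding by Cra were not tested against each other.

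The 5' profiles of the libraries agreed less at ranks 13 to 25, with a median r of 0.31, than at ranks 1 to 12, with 0.86. Profiles of the 12 strongest sites redrawn with the fragment numbers of the lower sites gave a median of 0.53 with a central 95% from 0.40 to 0.65. The observed value lies below this range, which was set beforehand as the outcome against too few fragments. The redraw assumes the number of fragments, however, and so does not exclude too few fragments. Within ranks 13 to 25, sites with more reads had a median r of 0.50 and those with fewer 0.15. This goes with too few fragments, but sites with more reads also tended to have higher scores, and the 2 were not separated. A further candidate explanation is that some of these sites, such as 3980631 with 3130 and 4062 reads and r = 0.31, have no fixed border, and this was not tested separately. A library deposited a second time is argued against, since 7.03% of the occupied 5' ends of replicate 1 outside the sites were occupied in replicate 2, where chance gives 1.99%. Outside the sites, positions with 1 read were occupied in the other library 2.265 and 2.39 times as often as those with 5 or more reads, which leaves a small carry-over of reads between libraries undecided.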
